A study of Homo sapiens with 12 samples.

How the data were processed

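CUT&RUN with a JUN antibody was carried out by the authors on primary human CD4+ memory T cells carrying a JUN-overexpressing (JUN_OE) or a control lentiviral vector, with the CUTANA ChIC/CUT&RUN kit and KAPA HyperPrep libraries. Each vector had 3 libraries with the JUN antibody and 3 with IgG; the IgG libraries were not used here. The submitters' notes name FastQC, Bowtie2, SAMtools, Picard, SEACR, bedtools, ChIPseeker, DiffBind, DESeq2 and HOMER, without versions or roles, and the genome build GRCh38 (hg38). Libraries were assigned to vectors and replicate numbers by the labels.

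The deposited site table gives signal as normalized read counts for 19658 sites of 401 bp, which the authors scaled so that all libraries had the same total over the sites. Every value was a whole multiple of 1 step per library within a tolerance of 0.1 reads, so whole reads were recovered by dividing by that step. The deposited peak lists, 1 per library, give the total signal and the maximum signal of each peak, from tracks that the authors scaled by 1 factor per library; their layout is that of relaxed SEACR calls. The maxima were whole multiples of 1 step, and the inverse of the step was taken as the fragment number of the library. That this is the number of fragments is an inference from the values. By it the libraries held 4.39, 5.03 and 5.59 M fragments in control replicates 1, 2 and 3 and 17.2, 7.62 and 5.92 M in the JUN_OE replicates. Reads recovered over the sites numbered 346833 to 550044 per control library and 974950 to 2004912 per JUN_OE library, with medians of 12, 21 and 13 and of 82, 48 and 39 reads per site. Sequencing reads are not independent molecules, so floors cover counting error only; where all control libraries had 0 reads, folds were computed against a floor of 3 reads over the group.

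Differences between the vectors were tested with limma 3.58.1 in R 4.3.3 (eBayes with a trend, moderated statistics) on log2 of the deposited value plus 1, two-sided, over all 19658 sites, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adding 1 shrinks fold changes at weak sites relative to adding less. In the control libraries 1 read was worth 1.64 to 2.60 units, so 1 is less than 1 control read. Where control libraries held few or no reads, fitted folds are therefore uncertain in size. They can be above or below those of edgeR on recovered reads, as with log2 fold changes of 2.81 against 1.81 near IL21 and 4.43 against 7.35 near IL2. The planned fit had the vector alone. The labels give libraries with the same replicate number the same source code in both arms, without saying what the code stands for. Correlations of the deviations from the vector's mean were 0.194, 0.191 and 0.0852 for libraries of the same number and below 0 for all others. Deviations from a vector's mean sum to 0 over its 3 libraries. The values below 0 therefore follow in part from those above 0 and are no separate evidence of pairing, which was not tested. Given the shared codes and these correlations, values with the replicate number as a block are given beside the planned ones. The counts of both fits had been seen when this was decided. Unless the block is named, an adjusted p comes from the fit by vector alone. The SE given is that of the fit by vector alone unless stated.

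Sites were named by a rule: the 15 largest increases and 10 largest decreases past the threshold that moved the same way in all 3 pairs, with a mean in the upper 50% of sites, 1 site per gene within 50 kb, or the 5 smallest p where fewer than 5 passed; up to 4 called sites from each of 17 gene lists; and all sites assigned to JUN, CXCL13, IL22, AHR, IL21, MAF, BATF, PRDM1, IFNG and IL2. The same rule was applied to the blocked fit after the data were examined. The lists covered peripheral and follicular helper (Tph and Tfh), IL22, Th17 and AHR, AP-1 family, interferon, Th1, Th2, Treg and TGF-beta, activation, naive and memory, inhibitory receptor, cytotoxic, T-cell core, B-cell, myeloid, CD8 and NK, stromal and housekeeping genes. A list's sites were those inside or within 50 kb of a member. Lists were tested with camera (correlation preset to 0.01, and estimated), with adjustment over the 17 lists.

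Gene positions came from a GRCh38.p14 gene table with 20033 protein-coding genes, which gives intervals without strands or transcripts. Distances were therefore taken to the gene's interval, and the planned classes by transcription start, exon and intron became within 3 kb of either end of a protein-coding gene, gene body and intergenic. No genome sequence was at hand, so the planned motif counts were not made. Shares of sites were compared by two-sided Fisher's exact tests over sites. Peak number, covered length, width and location were compared by two-sided exact permutation tests of 3 against 3 libraries, which cannot give a p below 0.10. Regions of a vector were merged peaks found in at least 2 of its 3 lists, and regions overlapping by at least 1 bp were shared.

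The alternatives covered the pseudocount, a filter on mean values of at least 10, median centring, quantile normalization, limma without a trend, array weights, the block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library. Added after the data were examined were scaling to inferred fragments, cyclic loess, restriction to sites with control peaks, thinning to 346833 reads per library, further blocked fits and leaving out each pair. The tests were tested on simulated data with 100 sites changed 4-fold and 100 changed 2-fold. With variation shared within pairs (SD 0.3 in log2), limma recovered 65% of 4-fold and 5% of 2-fold changes by vector alone, and 86% and 29% with the block, with 0 and 9 other sites called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the peaks and figures. No results are given for chromosome Y sites.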

Results

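JUN is a subunit of the AP-1 transcription factor. Its positions on chromatin were profiled by CUT&RUN, in which an antibody directs a nuclease to release DNA around the bound protein, in primary human CD4+ memory T cells. The cells carried a lentiviral vector that raises JUN (JUN_OE) or a control vector, and were kept for 72 h with CD3/CD28 beads, TGF-beta at 2 ng/mL and CH-223191, an inhibitor of the aryl hydrocarbon receptor (AHR), at 10 µM. The series concerns an AHR and JUN pathway and CXCL13-producing T cells in lupus. The comparison made here asks where the JUN signal differed between the vectors. It rests on 6 libraries made with the JUN antibody, 3 per vector. The 6 IgG libraries of the series were not analysed here, so no signal is set against a nonspecific antibody. Whole reads recovered over the 19658 sites of the deposited table numbered 346833, 550044 and 357279 in control replicates 1, 2 and 3, and 2004912, 1181302 and 974950 in the JUN_OE replicates. The median site held 12 to 21 reads in the control libraries and 39 to 82 in the JUN_OE libraries, so control values at weak sites carry the larger counting error.

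The JUN gene itself had 4 sites within 50 kb, and none lay inside it, so reads from the vector's copy of the coding sequence are not measured at these sites. At the site on the gene's upper end (chromosome 1, 58784046 to 58784446, GRCh38, centre 199 bp outside the gene), from which JUN is transcribed, the normalized count was 268 ± 7.96 in control and 103 ± 38.1 in JUN_OE libraries (SD, n = 3). This was 2.60-fold lower (log2 fold change −1.44, SE 0.24, adjusted p = 0.0499; 0.000219 with the replicate block), and lower in 3 of 3 pairs. The call was lost without JUN_OE replicate 2 (log2 fold change −1.17, adjusted p = 0.287) and without JUN_OE replicate 3 (log2 fold change −1.44, adjusted p = 0.251). These values assume an equal total over the sites in every library. Scaled instead to the fragments inferred for each library, the log2 fold change was −0.63 (SE 0.41, paired fit, adjusted p = 0.190), which did not pass. The other 3 sites, all outside the gene, passed in neither fit.

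JUN_OE libraries yielded more and wider peaks that covered more of the genome. The lists held 9385 ± 2086 peaks in control and 21798 ± 3898 in JUN_OE libraries (SD, n = 3), a 2.32-fold difference in means, and 1.75-, 2.39- and 3.06-fold in pairs 1, 2 and 3. The peaks covered 13.0 ± 3.17 Mb in control and 45.4 ± 8.55 Mb in JUN_OE libraries, 3.49-fold more, and their median width was 1284 ± 94.5 bp against 1855 ± 375 bp. For each of the 3 measures the groups did not overlap, which gave p = 0.10 in a two-sided exact permutation test, the smallest that 3 against 3 libraries allow. The number of fragments inferred per library also differed, 4.39 to 5.59 M in control and 5.92 to 17.2 M in JUN_OE libraries. In pair 3, with 5.59 and 5.92 M fragments, the peak numbers were 6994 and 21395 and the median widths 1313 and 1516 bp, the smallest difference in width of the 3 pairs.

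In the lists as deposited, which differ in length, the JUN_OE regions covered nearly all control regions and many others. Of 8344 regions with a peak in at least 2 control lists, 8233 (98.7%) overlapped the 19863 regions found in at least 2 JUN_OE lists, and 11982 JUN_OE regions had no control region (7898 without JUN_OE replicate 2). With 50% reciprocal overlap required, 5349 control regions matched a JUN_OE region. With each list reduced to its strongest 6994 peaks, most regions of both vectors were shared: 78.4% of 6283 control regions and 71.3% of 6634 JUN_OE regions, leaving 1356 and 1904. In the site table, 7864 sites had peaks in at least 2 JUN_OE lists and no control list, and 11 sites the reverse. The share of inferred fragments lying in the sites was 8.41 ± 2.31% in control and 14.5 ± 2.54% in JUN_OE libraries (SD, n = 3), higher in 3 of 3 pairs. Of the sites, 14361 had peaks in 3 of 3 JUN_OE lists and 4460 in 3 of 3 control lists, which itself favours a higher JUN_OE share. The mean fold over the pairs was 1.82 ± 0.65 for all sites. It was 1.62 ± 0.60 for the 7554 sites with peaks in at least 2 control lists.

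**Figure D1:**
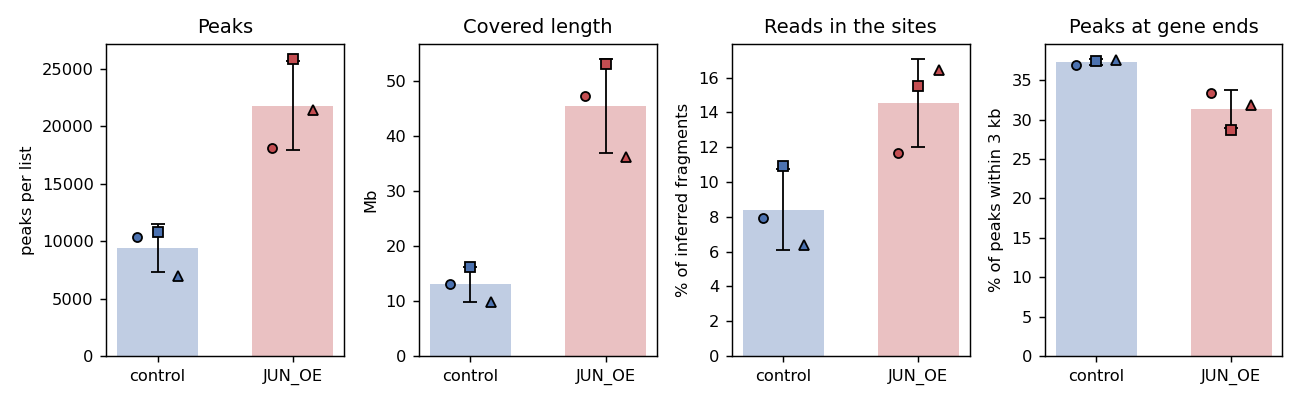
Peaks per list, covered length in Mb, reads in the 19658 sites as a percentage of inferred fragments, and the percentage of peaks within 3 kb of an end of a protein-coding gene, for control and JUN_OE libraries. Bars are means, error bars the SD over 3 libraries, and points single libraries, with 1 marker per replicate number; the first 3 measures were higher in all JUN_OE libraries and the last was lower. More sites had peaks in 3 of 3 JUN_OE lists (14361) than in 3 of 3 control lists (4460), which favours a higher JUN_OE share of reads in the sites.

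At single sites, 5 were higher and 9 lower in JUN_OE libraries in the fit by vector alone. The 5 higher sites lay in PRKCH, a protein kinase C gene active in T cells, SPART, PLCL2 and PDE8B and 4.96 kb from MRPL15. The site in PRKCH (chromosome 14, 61219469 to 61219869) went from 16.4 ± 8.45 to 89.7 ± 14.4 (5.46-fold, log2 fold change 2.47, SE 0.36, adjusted p = 0.0434). The largest decrease among these sites was at a site 50.2 kb from ANKRD10 (chromosome 13, 110965068 to 110965468), from 187 ± 36.7 to 24.3 ± 3.81 (log2 fold change −2.88, SE 0.25, adjusted p = 0.000429). The other lower sites were in or near CIC, IMPG2, TUBA1A, WEE1, ATF3 and JUN, 67.4 kb from KLF6 and 87.4 kb from TACR3. ATF3, a stress-induced AP-1 family member, had 159 ± 7.54 and 67.9 ± 6.69 at a site 6.3 kb away. Of these sites, those in PLCL2 and PDE8B and near ANKRD10, TACR3 and KLF6 fell outside the rule for named sites and are given after their values were seen. The next 5 increases, which did not pass, were at NR2C2, ANKS1A, FAM24B, SPECC1L and a site 19.9 kb from IL2, all with adjusted p = 0.0529.

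The number of sites depended strongly on the fit. With the replicate number as a block, limma called 900 sites higher and 498 lower, all 14 sites above among them. Leaving out control replicate 1, 2 or 3 from the fit by vector alone gave 217, 204 and 130 higher and 50, 65 and 18 lower sites, and leaving out JUN_OE replicate 1, 2 or 3 gave 1, 0 and 0 higher and 8, 1 and 1 lower. Without pair 2 the blocked fit called 46 higher and 76 lower. The balance of directions also followed the scaling: 19 higher and 65 lower after median centring, 51 and 17 after quantile normalization, and 6589 and 3 when scaled to inferred fragments, which moved the median log2 fold change of all sites from 0.16 to 0.93. Of the 900 sites higher in the blocked fit, all 900 passed as higher with fragment scaling and the block. Of the 498 lower sites, 4 passed as lower (near ANKRD10 and TACR3 and in IMPG2 and DUSP16), none as higher, and 202 changed sign. The upward shift of the median favours increases over decreases, so these counts do not show that the increases are the firmer calls.

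Named by the same rule in the blocked fit, the largest increases were in PRKCH, SPART, NR2C2, LOXL2, DNAJC17, IFT57, TOP1, TLK1, MAPKAP1, FGF1 and NOTCH2, and near PSG1, TSPAN9, COMMD7 and MRPL15. NOTCH2, which encodes a receptor of the Notch pathway, had 17.7 ± 13.1 and 59.2 ± 2.98 (log2 fold change 1.90, SE 0.43, adjusted p = 0.0662, 0.00646 with the block). The decreases were at IMPG2, DUSP16, YWHAH, JUND, JUN, THAP4, BCL6B, TUBA1A, LYSMD4 and OS9. DUSP16, a phosphatase of MAP kinases, fell from 91.9 ± 9.61 to 27.4 ± 13.3 (adjusted p = 0.0529, 0.00161 with the block). This use of the rule was added after the data were examined.

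Single sites near IL22, IL21, IL2 and BATF rose in the blocked fit, while no site at CXCL13 did. These risen sites had peaks in 0 control lists and in 3, 2, 2 and 3 JUN_OE lists. Being listed through JUN_OE peaks itself favours a higher value in JUN_OE libraries. The CXCL13 site with the highest counts had peaks in 3 control and 3 JUN_OE lists. Over all 19658 sites the blocked fit called 900 higher and 498 lower. No test was made of whether any of these genes departs from that share. A site 6.0 kb from IL22, a cytokine acting on epithelia (chromosome 12, 68259401 to 68259801), had 42.9 ± 13.8 in control and 98.7 ± 22 in JUN_OE libraries (2.30-fold, log2 fold change 1.2, SE 0.28, adjusted p = 0.0723, 0.00826 with the block), higher in 3 of 3 pairs. Without pair 2 the blocked log2 fold change was 1.02 (adjusted p = 0.109). The other 7 sites near IL22 passed in neither fit. A site 25.6 kb from IL21, a cytokine of T cells that help B cells, had 5.79 ± 7.88 and 26.2 ± 4.59 (adjusted p = 0.112, 0.0262 with the block). Its blocked log2 fold change of 2.81 was 3.92 without pair 2 (adjusted p = 0.0889) and 1.71 without pair 3 (adjusted p = 0.137). The site near IL2 (chromosome 4, 122476452 to 122476852) held 0 reads in all 3 control libraries and 91 in the JUN_OE libraries, at least 9.64-fold higher against a floor of 3 reads over the control group (adjusted p = 0.0529, 0.0107 with the block). Its blocked log2 fold change of 4.43 was 4.38 without pair 2 (adjusted p = 0.128). A site 9.2 kb from BATF, an AP-1 family member of activated T cells, had 7.82 ± 5.30 and 29.9 ± 2.09 (adjusted p = 0.101, 0.0316 with the block). Its blocked log2 fold change of 2.02 was 2.11, 2.52 and 1.43 without pairs 1, 2 and 3 (adjusted p = 0.0573, 0.107 and 0.147). With the block, cyclic loess, which removes trends with signal strength, ended the calls at IL21 (adjusted p = 0.129) and BATF (0.177) as the log2 fold changes became smaller at similar SE, from 2.81 (SE 0.75) to 2.16 (SE 0.77) at IL21 and from 2.02 (SE 0.56) to 1.42 (SE 0.57) at BATF. Thinning to equal reads ended those at IL22 (0.0575), IL2 (0.0723) and BATF (0.0696) with folds of similar size and larger SE: 1.2 (SE 0.26) and 1.17 (SE 0.31) at IL22, and 2.02 (SE 0.56) and 2.22 (SE 0.62) at BATF. At IL2, with 0 control reads, the fitted fold depends on the pseudocount, and its SE went from 1.0 to 1.15.

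CXCL13, the B-cell-attracting chemokine named in the series title, had 5 sites, all inside the gene, and none passed in either fit. Its site with the highest counts (chromosome 4, 77586949 to 77587349) had 121 ± 35.1 and 89.3 ± 24.2 (log2 fold change −0.42, SE 0.27, adjusted p = 0.398, 0.220 with the block), and it was lower in 3 of 3 pairs while the ranges of the vectors overlapped. Scaled to fragments, its log2 fold change was 0.38 and did not pass. The fits scaled to fragments were those in which any CXCL13 site passed, with 2 of the 5 higher. None of the 4 sites near AHR, the receptor inhibited in all samples, of 11 at MAF, 8 at PRDM1 and 4 near IFNG passed in either fit. With fragment scaling and the block, 1, 4, 3 and 0 of them passed as higher. So did 7 of 8 sites near IL22, 4 of 6 near IL21, 1 of 6 near BATF, 1 of 3 near IL2 and 0 of 4 near JUN. Over all 19658 sites, 7562 passed as higher with that scaling and the block. No test was made of whether any gene departs from that share.

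**Figure D2:**
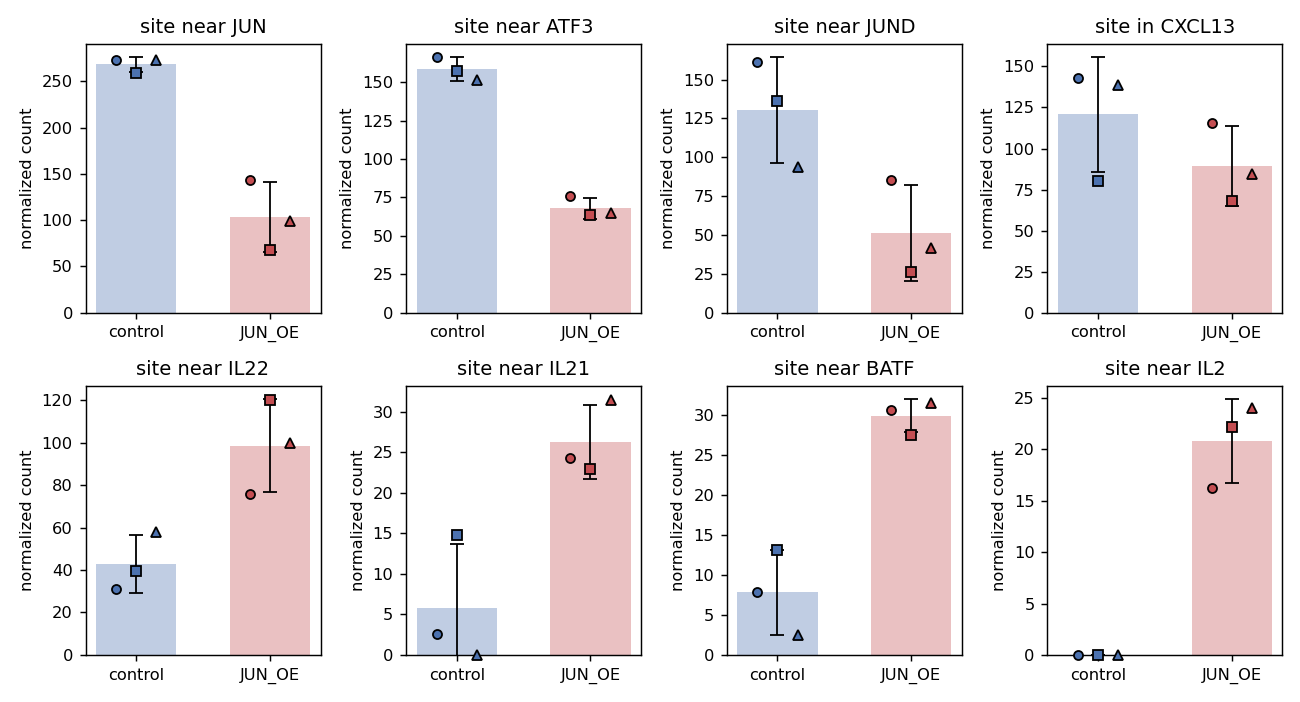
Normalized counts at 1 site each near JUN, ATF3, JUND, IL22, IL21, BATF and IL2 and in CXCL13 in control and JUN_OE libraries. Bars are means, error bars the SD over 3 libraries, and points single libraries, with 1 marker per replicate number; the counts at JUN, 268 and 103 on average, do not overlap between the vectors, and those at CXCL13 overlap and change the sign of their difference with scaling to fragments.

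With all their sites, the 17 gene lists, fixed like the tests and the naming rule before the data were examined, did not differ as groups from all other sites in limma's camera, by vector alone or with the block (adjusted p above the threshold for all; 1 list at an unadjusted p under 0.05 in each). With 1 site per gene, the strongest, by vector alone, 2 lists were lower, the AP-1 family (adjusted p = 0.00622) and the T-cell core (adjusted p = 0.0174). The sites so chosen had a median value of 71.8, against 35.3 for all sites. Strong sites were lower in general under equal totals (median log2 fold change −0.25 in the strongest of 10 groups), so this choice itself favours a lower result. Neither passed with an estimated correlation (adjusted p = 0.258 for both) or after cyclic loess (0.589 and 0.673), and the shift was not confined to them: 7 of the 17 lists had an unadjusted p under 0.05 and 15 the direction down. With all sites the AP-1 family list had the smallest adjusted p (adjusted p = 0.218, direction down; adjusted p = 0.611 with an estimated correlation and 0.255 with the block). Its 100 sites included 2 lower and 0 higher by vector alone (3 lower adjusted over the list alone), at JUN and ATF3. With the block 4 fell and 2 rose, also when adjusted over the list alone, and none of the 4 decreases passed when scaled to fragments. With cyclic loess and the block, 3 of the 4 decreases and 0 of the 2 increases passed, the latter with log2 fold changes of 2.69 (SE 0.71) before and 2.04 (SE 0.72) after at BACH2 and those given above at BATF. JUND, at 130 ± 34.3 and 51.1 ± 30.9, was among the former (adjusted p = 0.0762, 0.00284 with the block), and BACH2, a repressor that competes at AP-1 sites, at 5.51 ± 5.76 and 26.7 ± 6.53, among the latter (adjusted p = 0.113, 0.0244 with the block), while another site in BACH2, outside the naming rule, fell (adjusted p = 0.0406 with the block). The list's median log2 fold change was −0.05 and its mean 0.05; for the interferon list these were −0.05 and 0.14 and for the stromal list −0.14 and 0.16, each with the direction down in camera, which sets a list against all other sites. For the other 16 lists, by vector alone, 0 of 765 sites passed in limma over all sites, while 114 had an unadjusted p under 0.05, 18 passed in edgeR and 15 in DESeq2. Over all 19658 sites, 3939 had an unadjusted p under 0.05 in limma, and 659 passed in edgeR and 554 in DESeq2. Adjusted over the list alone, by vector alone, the interferon and activation lists each had 1 higher and 1 lower, the naive and memory list 2 higher, and the Th1 and housekeeping lists 1 lower each.

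The following counts are from the blocked fit, which called 49 list sites, 26 higher and 23 lower. Over all 19658 sites it called 900 higher and 498 lower, and the count of no single list was tested against that share. Of the 49 list sites, 12 passed in the same direction with cyclic loess and the block, and 11 with thinned reads and the block. None of the calls that ended changed sign. In the naive and memory list 6 of 101 sites rose and 0 fell, and those sites were near 3 genes: LEF1, at 7.05 ± 4.07 and 35.2 ± 5.19, ETS1, at 1.73 ± 3 and 21.9 ± 7, and FOXP1, all transcription factors of resting T cells. The site named by the rule for each of the 3 genes had peaks in 0 control lists, which itself favours an increase. Of these 6 sites, 0 passed with cyclic loess and the block, where all 6 stayed positive with an unadjusted p under 0.05 and their median log2 fold change went from 2.05 to 1.57 at a median SE of 0.54 in both. With thinned reads and the block 2 passed, and the other 4 had a median of 1.7 (median SE 0.49) before and 1.74 (0.61) after. In the T-cell core list 0 of 69 rose and 4 fell, among them sites near CD2 and CD5 and in CD247, a chain of the T-cell receptor complex; CD2 had 294 ± 33.8 and 182 ± 29.1 (1.62-fold lower, adjusted p = 0.0813, 0.00985 with the block). The sites named near CD2, CD5, CD27 and CD247 changed sign when scaled to fragments, and with the block 0 of the 4 passed after cyclic loess (adjusted p from 0.167 to 0.342) and 1 with thinned reads. After loess their median log2 fold change went from −0.69 to −0.40 at a median SE of 0.19 in both. The 3 calls that ended with thinned reads had a median of −0.68 (median SE 0.20) before and −0.58 (0.22) after. In the IL22, Th17 and AHR list 3 of 80 rose, 1 near IL22 and 2 in RORA, and 1, at CCR6, fell (3 and 0 adjusted over the list alone). In the Tph and Tfh list 1 of 87 rose, near IL21, and 2 fell, in TOX and CD200 (0 and 0 adjusted over the list alone).

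Of the remaining lists in the blocked fit, the Treg and TGF-beta list had 3 of 93 higher, in SMAD2 and TGIF1 and 28.7 kb from ITGA1, and 2 lower, near TGFB1 and IKZF4, which changed sign with fragment scaling. The activation list had 2 of 82 higher, near IL2 and NR4A1, and 2 lower, in NR4A1 and 45.9 kb from IL2RB. The ITGA1 site, the lower NR4A1 site and the second RORA site were chosen after their values were seen. The inhibitory receptor list had 2 of 55 higher (VSIR, ENTPD1) and 2 lower (CD101, CD244). The interferon list had 1 of 49 higher, in IFNAR2, and 2 lower, near IRF7 and in ISG20, the latter changing sign with fragment scaling. The Th1 list had IL12RB2 higher and RUNX3 lower among 45 sites, the Th2 list IL1RL1 higher and STAT6 lower among 22, and the cytotoxic list FASLG higher among 30. Genes were assigned by distance, and the sites near IRF7, IKZF4, TGFB1, STAT6, IL2RB, VSIR, CD101, CD27, ITGA1, ITGAM, B2M and GAPDH, the higher site near NR4A1 and 1 of the 3 LEF1 sites (16.2 kb away) lay in or closer to another gene. Among markers of other cells, 0 of 22 B-cell sites passed (1 at an unadjusted p under 0.05 with the block, 0 in edgeR), while the myeloid, CD8 and NK, and stromal lists had 1 higher site each, at ITGAM, CD8A and COL3A1. In the housekeeping list 2 of 34 fell, near B2M and GAPDH, and GAPDH changed sign with fragment scaling. ITGAM had 87.2 ± 20.5 and 140 ± 15.3, CD8A 7.05 ± 4.07 and 27.4 ± 8.78, and COL3A1 4.97 ± 4.92 and 21.2 ± 2.63, and none of these 3 passed by vector alone.

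Gene ends held a smaller share of JUN_OE peaks. Peaks within 3 kb of either end of a protein-coding gene were 37.3 ± 0.39% of control and 31.4 ± 2.38% of JUN_OE peaks, while peaks in gene bodies were 34.1 ± 1.37% and 40.5 ± 1.48% (SD, n = 3). The groups did not overlap in either share (two-sided exact permutation test, p = 0.10, the smallest possible). With each list reduced to its strongest 6994 peaks, the shares at gene ends were 38.1 ± 0.62% and 33.5 ± 2.69%. For intergenic peaks the shares were 28.5 ± 1.17% and 28.1 ± 1.02% (p = 0.80 in the same exact permutation test). Among the sites of the table, 12.0% of the 900 higher in the blocked fit lay at gene ends, against 33.1% of those not past the threshold (Fisher's exact test over sites, odds ratio 0.28, adjusted p = 1.5e-45), and 47.4% of the 498 lower (odds ratio 1.82, adjusted p = 1.4e-10). By vector alone, 1 of the 5 higher (20%, odds ratio 0.52) and 3 of the 9 lower sites (33.3%, odds ratio 1.04) lay there, against 32.5% of the others (Fisher's exact test, adjusted p = 1 for both). Sites are not independent replicates, and these comparisons did not match sites for strength. Most lower sites of the blocked fit lay in the strongest of 10 equal groups, which held 774 gene-end sites and 1192 others. The weakest group held 515 and 1451. With cyclic loess and the block, 14.2% of higher sites lay at gene ends, which passed Fisher's exact test. Of the lower sites 37.7% lay there, which did not pass, while 35.4% within 1 kb did. Scaled to fragments, the median log2 fold change was 0.73 at gene ends, 1.08 in gene bodies and 0.99 between genes. Under that scaling gene-end sites as a whole were lower only relative to the others. With equal totals these medians were −0.05, 0.30 and 0.21. Which scaling gives the absolute direction was not tested.

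**Figure D3:**
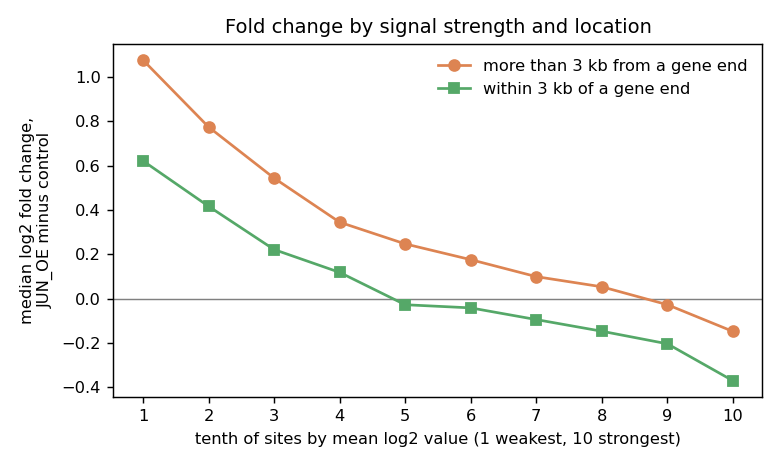
Median log2 fold change, JUN_OE minus control, of the deposited normalized counts for 10 equal groups of sites ordered by mean log2 value, for sites within 3 kb of a gene end and for the others. Points are medians over sites; the line for sites away from gene ends lies above the other in all 10 groups, with differences from 0.18 to 0.46, and both are higher in the weakest group than in the strongest.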

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

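The tests with fragment scaling, cyclic loess, sites with control peaks, thinned reads, edgeR with the block, median centring with the block, left-out pairs with the block, location within 1 kb or with the block in edgeR or loess, peaks at gene ends with equal list lengths, and 1 site per gene with an estimated correlation or loess were chosen after the data were seen. The counts of differential sites changed with nearly every choice, and the cause was not tested except where the construction shows it. Against 5 higher and 9 lower sites in limma by vector alone (3939 at an unadjusted p under 0.05), the counts were 0 and 2 with a pseudocount of 0.5, 431 and 188 with a pseudocount of 8, 11 and 26 for sites with a mean of at least 10, 19 and 65 with median-centred libraries, 51 and 17 with quantile normalization, 6 and 1 without the trend, 331 and 3.3e+02 in edgeR (659 in all), 78 and 476 in DESeq2, and 222 and 79 with array weights. They were 900 and 498 with the replicate block, 809 and 917 in edgeR with the block, and 691 and 863 with median-centred libraries and the block. Scaling to fragments gave 6589 and 3, or 7562 and 4 with the block. Cyclic loess gave 0 and 1, or 316 and 130 with the block. Sites in 2 or 3 control lists gave 31 and 148, or 166 and 551 with the block, and thinned reads 8 and 13, or 148 and 144 with the block. Leaving out 1 library gave 0 to 217 higher and 1 to 65 lower sites, and leaving out pair 1, 2 or 3 from the blocked fit gave 624, 46 and 730 higher and 323, 76 and 415 lower.

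All 14 sites called by vector alone passed in the same direction with the block, in edgeR, with a pseudocount of 8, with array weights, with median centring, with the mean filter and without each control library in turn. DESeq2 kept 12, quantile normalization 11, thinned reads 10, sites in control lists 9 (those it tested), fragment scaling 8, the fit without JUN_OE replicate 1 kept 5 and the pseudocount of 0.5 kept 2, and the fits without the trend, with cyclic loess, without JUN_OE replicate 2 and without JUN_OE replicate 3 kept 1 each. None of the 14 reversed.

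The JUN site, at −1.44 (adjusted p = 0.0499), missed the threshold at −1.44 with a pseudocount of 0.5 (0.0678) and without the trend (0.139), at −1.12 with quantile normalization (0.0570) and cyclic loess (0.103), and at −0.63 scaled to fragments (0.129; 0.190 with the block). Leaving out 1 library gave −1.70 to −1.17, with adjusted p from 0.0348 to 0.287, and leaving out a pair from the blocked fit gave −1.69 to −1.19. It stayed negative in every fit run.

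Scaled to fragments, with or without the block, these log2 fold changes turned from negative to positive, none past the threshold: CD2 0.11, CD247 0.12, CD27 0.085, CD5 0.17, CXCL13 0.38, GAPDH 0.13, IFNG 0.39, IKZF4 0.18, ISG20 0.22 and TGFB1 0.17. This scaling applies 1 factor to all sites of a library. It raised JUN_OE values relative to control because a larger share of their inferred fragments lay in the sites. That share was 1.48-, 1.42- and 2.58-fold higher in pairs 1, 2 and 3. No other named site reversed in any fit.

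No gene list passed in camera by vector alone; with 1 site per gene, 2 lists were lower (AP-1 family, adjusted p = 0.00622, and T-cell core, 0.0174), against 0 in the estimated-correlation, median-centred, blocked, loess and left-out-library settings and 0 with 1 site per gene and an estimated correlation or loess. For the AP-1 list the adjusted p ranged from 0.00622 to 0.708. Taking 1 site per gene, the strongest, itself favours a lower result under equal totals.

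Of sites called higher, 12.0% lay at gene ends with the block, 9.67% in edgeR, 11.4% in edgeR with the block and 14.2% in loess with the block; within 1 kb these were 4.89%, 3.63%, 4.57% and 6.33%. Of sites called lower, the shares were 47.4%, 44.2%, 46.9% and 37.7%, and within 1 kb 42.6%, 39.9%, 42.2% and 35.4%. All passed Fisher's exact test except the lower sites in loess within 3 kb (adjusted p = 0.325), while by vector alone the 5 higher and 9 lower sites (20% and 33.3%, against 32.5% of the others) showed no difference that passed (adjusted p = 1), the lower sites being close to the others.

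The fold in peak number was 2.06 to 2.52 and that in median width 1.29 to 1.58 in all settings run. The fold in covered length, 3.49, was 3.72 for peaks at or above the pooled median maximum and 3.11 to 3.97 without 1 library. The difference at gene ends was −7.01 to −4.68 points without 1 library, −6.89 within 1 kb and −4.53 with equal list lengths. Against 8344 control regions there were 4914 when all 3 lists were required and 5371 to 8344 without 1 library. Against 19863 JUN_OE regions there were 6634 with equal list lengths and 15634 to 19863 without 1 library. Regions of JUN_OE alone, 11982, became 1904 with equal list lengths and 7898 to 14747 without 1 library. Regions of control alone, 111, became 2995 with 50% reciprocal overlap, 41 with all 3 lists required, 1356 with equal list lengths and 28 to 308 without 1 library. The planned motif counts and their alternatives, and the classes by transcription start, exon and intron, were not run for want of a genome sequence and transcripts. The control libraries held a median of 12 to 21 reads per site. In simulated data 18% of 2-fold changes passed by vector alone without variation shared within pairs and 5% with it, or 17% and 29% with the block, so most 2-fold changes were missed there. The simulation changed 100 sites 4-fold and 100 sites 2-fold, fewer than the 1398 called with the block in the data. The adjustment depends on that number, so recovery in the data may differ. Recovery was not measured by site strength.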

Other observations

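The tests of diffuse background, of the threshold and depth behind the peak numbers, of the scaling at JUN and of other splits of the samples were chosen only after the result was seen. Peak counts at single loci were as follows. Within 50 kb of CXCL13, the gene body included, the lists held 2.0 ± 1.0 peaks in control and 5.33 ± 0.577 in JUN_OE libraries (SD, n = 3). Near IL22 there were 2.0 ± 1.0 and 8.0 ± 2.65 peaks, and near IL2 0.333 ± 0.577 and 3.0 ± 1.0. Near JUN there were 3.0 ± 1.0 and 4.0 ± 0.0, and near IFNG 3.0 ± 1.0 and 4.33 ± 0.577. The loci come from the same 6 lists, which differed 2.32-fold in length, and no test was made of whether any locus departs from that ratio.

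The fold in peaks was 1.75, 2.39 and 3.06 in pairs 1, 2 and 3, whose fragment numbers differed by factors of 3.92, 1.51 and 1.06. The value against depth as the whole cause of the longer lists is that of pair 3 alone. The share of fragments in sites with control peaks was higher in JUN_OE libraries in 3 of 3 pairs, by log2 ratios of 0.37, 0.32 and 1.2 (mean 0.63 ± 0.50, SD, and 0.35 ± 0.036 without pair 3). A calling threshold does not change the fragments in a fixed set of sites, so this share cannot decide whether a looser threshold lengthened the JUN_OE lists. The lowest peak maximum was 2, 3 and 3 inferred fragments in control replicates 1, 2 and 3 and 6, 3 and 2 in the JUN_OE replicates. A looser threshold stays open.

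In the 7554 sites with a peak in at least 2 control lists, 5.60 ± 1.47% of inferred fragments lay there in control and 8.57 ± 1.47% in JUN_OE libraries. In the 7982 sites with no control peak these shares were 1.48 ± 0.41% and 3.52 ± 0.66% (SD, n = 3). No difference between these site sets was tested.

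Weak sites gained relative to strong sites in JUN_OE libraries: the median log2 fold change was 0.95 in the weakest of 10 equal groups of sites and −0.25 in the strongest, a gap of 1.2, while scaled to fragments these were 1.60 and 0.55, so that the strongest group was lower under equal totals and higher under fragment scaling. With all libraries thinned to equal reads the gap was 1.10, which argues against read depth at these sites as its cause. Thinning keeps the site list, so it cannot decide whether depth acted through which sites were listed. The share of fragments in sites with control peaks was higher by a mean log2 ratio of 0.63 ± 0.50 (SD, 3 pairs; 0.35 without pair 3), where more diffuse background alone would lower it. A rise in signal at these sites could outweigh a rise in background elsewhere. The share therefore cannot decide whether background also rose, and no IgG library was used. Among sites with control peaks the gap was 0.34, below 50% of the whole as a site list drawn mainly from JUN_OE peaks would give, but choosing sites by control peaks favours those high in control, so this cannot be told apart from the selection itself. The biological alternative, a hypothesis that raised JUN may spread to sites it seldom occupies in control cells, stays open and untested; JUN signal over IgG at sites listed without regard to vector would test it.

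Sites away from gene ends gained relative to those at gene ends. Because gene-end sites were on average stronger, the fall of strong sites relative to weak ones, which under fragment scaling is a smaller rise, could have given this, but the difference was above 0 in 10 of 10 groups of equal strength (0.18 to 0.46), which argues against it as the whole cause. A site list drawn mainly from JUN_OE peaks and differences in background at open chromatin, for which IgG libraries would be needed, were not tested. That JUN may bind more at distal elements when raised is a hypothesis from the same data, which IgG-corrected signal at such sites would test.

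The lower signal at the start of JUN (−1.44) was −1.12 (SE 0.19) after cyclic loess with the block, so the fall of strong sites relative to weak ones does not account for all of it. Scaled to fragments with the block it was −0.63 (SE 0.41), neither at 0 or above nor below it by 2 SE, so the scaling to equal totals cannot be told apart from a real decrease. That less JUN may be bound at its own gene in cells with the vector is a hypothesis that stays open, and scaling to added spike-in DNA would test it.

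For the counts of differential sites, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 14 sites, the highest other 0, so 1 split of 10 gave as many. Of the 4 splits that part all 3 pairs, 1 gave as many in the blocked fit, the real one with 1398 sites against 0 in the highest other, and 4 splits are likewise too few.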
